A study of Acinetobacter venetianus RAG-1 = CIP 110063 with 4 samples.

How the data were processed

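RNA-seq libraries of Acinetobacter venetianus RAG-1 were compared across 4 physiological states, with 1 library per state. Per the labels' protocols, total RNA was taken with a commercial bacterial kit, ribosomal RNA was depleted, and a stranded library kit was used. All 4 libraries carry the same batch label, and nothing in the labels gives a replicate of any state. The aligner, the counting program, the genome build and the annotation version are not given in the sources used here.

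Each library came with 2 tables over 3282 genes. The first holds the authors' raw read counts per gene, as whole numbers, per the file headers. The second holds FPKM values that the authors deposited, per the file headers. Dividing the counts by the FPKM values gave 1 length per gene and 1 library factor per library. The authors' FPKM factors stood to one another exactly as DESeq2 median-of-ratios size factors computed here from the deposited counts do (0.835, 0.844, 1.32 and 1.08 for HR, ER, DT and AT, relative to their geometric mean), and not as the total counts do (0.976, 0.983, 1.03 and 1.02). FPKM values deposited this way are comparable between libraries, but they do not add up to a like sum in each library.

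Gene lengths were recovered from the same quotient, at the scale that makes every length a whole number of base pairs. All 3251 genes with a count in some library then lay within 0.0106 bp of a whole number. Of the lengths, 97.8% were multiples of 3 and 72 were not, so most are taken to be coding lengths. A multiple of 3 does not by itself show that a given gene codes for a protein. The other 31 genes had no count in any library.

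The files identify genes by RefSeq-style locus tags (F959_RS numbers) and do not pair them with gene symbols or products, and no annotation was used here. The 33 gene lists that had been fixed before the data were examined could therefore be matched to 0 genes, and no list, symbol or product is reported. The fallback fixed with them was applied: for each comparison, the 2 highest and 2 lowest ratios among genes with at least 50 counts in the library with more reads are named by their tag. The fallback gave the number of tags and not their ranking, which was taken from the naming rule it stands in for. Groups of genes are otherwise described by their size of change, their course over the states, their length or their place in the tag order. The main comparisons, the thresholds and the alternative settings were also set before the data were examined.

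With 1 library per state, no test across samples can be made and no p-value is given. Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), which multiplied the library totals by 0.863 (HR), 0.865 (ER), 1.27 (DT) and 1.05 (AT). Levels are given as CPM of these scaled totals, made here. Ratios are on the log2 scale with a prior count of 0.5, and a gene was counted as higher or lower when its ratio reached 2-fold and the library with more reads held at least 20 counts. Each ratio has an exact 95% interval (Clopper-Pearson on the split of the summed counts, scipy 1.17.1, Python 3.11.15). These intervals cover counting error only: they say nothing of how 2 cultures or 2 electrodes of the same state would differ, and reads without molecular identifiers are not independent molecules. A fold against a library with no count was computed at a floor of 3 counts in that library.

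Library totals were 6560867 counts for HR, 6608134 for ER, 6905977 for DT and 6825279 for AT. A count of 0 allows up to 3 counts of the total, which is 0.457, 0.454, 0.434 and 0.440 CPM of unscaled counts, in the same order. The median width of the 95% counting interval over compared genes was 0.44 on the log2 scale for ER against HR and 0.37 for AT against DT.

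The ratio code was tested on data simulated for ER against HR over all 3282 genes, with Poisson counts and 200 changed genes, 50 of each fold size. It counted 0% of the genes changed 1.5-fold, 98% of those changed 3-fold and every one of those changed 4-fold or 8-fold. It counted 0.21% of the 2915 compared genes that were not changed, and their intervals held the true value in 95.8% of cases. This simulation contains counting error and no difference between cultures.

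The alternative settings were total-count scaling, median-of-ratios scaling (DESeq2 1.42.0), TMM without the 20 most counted genes, the deposited FPKM with a pseudocount of 1, no count filter, a minimum of 100 counts, a prior count of 5, thinning to the smallest library, a whole counting interval beyond 2-fold, and a 4-fold threshold. Stable RNA genes could not be picked out by name in the scaling that leaves out the 20 most counted genes, so only those 20 were left out. A further alternative was chosen after seeing the data: an even level of 2.47 scaled CPM per kilobase, measured in the genes with the lowest HR level against an offset of -0.09 (log2) of DT to ER in the genes with higher HR levels, was taken off the DT counts.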

Results

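Acinetobacter venetianus RAG-1 is an oil-degrading bacterium known for its bioemulsifier emulsan. Its transcriptome was measured in 4 states to follow the passage between respiration on organic matter and respiration fed by a cathode during sensing of biochemical oxygen demand (BOD), a measure of degradable organic matter in water. The states were planktonic cells grown heterotrophically (HR), an electrode biofilm at its stable baseline current (ER), the biofilm during a BOD test at the lowest current (DT), and the biofilm after the electrolyte was replaced and the current had settled again (AT). The sample titles give 15 h of culture for HR, 3 days on the cathode for ER, 2 h of BOD exposure for DT and 2 h of recovery for AT, at 30 °C. For HR the labels disagree: its title names LB medium, and the protocol names nutrient broth and logarithmic phase. There was 1 library per state, with 6560867 (HR), 6608134 (ER), 6905977 (DT) and 6825279 (AT) gene counts, so each difference below compares 2 libraries, has no replicate check, and carries an interval for counting error only. Genes are given by locus tag because the files pair the tags with no names.

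A few genes held much of each library. F959_RS16585, 360 bp long, took 24.5% of all counts in ER, against 8.4% in HR, 7.58% in DT and 16.8% in AT. F959_RS16390, 356 bp long, took 6.19% in ER, 3.45% in HR, 1.22% in DT and 3.94% in AT. Both were chosen after their values were seen, and the exact 95% binomial intervals of these shares were at most 0.066 percentage points wide. A gene of 270 bp held 7.59% of the HR counts and 0.725%, 0.255% and 0.665% of those of ER, DT and AT, and a gene of 1512 bp held 7.31% in HR, 1.69% in ER, 4.31% in DT and 3.16% in AT. The 10 most counted genes of each library together took 35.4% in HR, 38.7% in ER, 23.2% in DT and 32.2% in AT.

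The 3 biofilm libraries were more alike than any of them was to HR. Across genes, Spearman's rho was 0.951 between ER and DT, 0.947 between AT and either ER or DT, and 0.835 (ER), 0.862 (DT) and 0.893 (AT) against HR. The SD of the log2 ratios was 0.73 for DT over ER, 0.74 for AT over ER and 0.73 for AT over DT. Against HR it was 1.38 for ER, 1.25 for DT and 1.101 for AT. Of the genes compared with HR, 37.6% differed at least 2-fold in ER, 31.3% in DT and 26.4% in AT.

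The comparison of ER with HR asks what differs between growth on the cathode and heterotrophic growth. Of 3129 genes compared, 590 were at least 2-fold higher in ER and 585 at least 2-fold lower, and 71 in each direction differed at least 8-fold. The highest ratio was that of F959_RS08475 (597 bp), at 1209 TMM-scaled CPM in ER and 3.71 CPM in HR, a 319.6-fold difference (95% counting interval 213 to 527). F959_RS06180 (1041 bp) stood at 1173 against 4.59, which is 251-fold (174 to 391). On the low side, F959_RS00615 (1059 bp) stood at 2449 CPM in HR and 21.0 CPM in ER, 116-fold lower (97.4 to 141). F959_RS11880 (77 bp) had 59 counts in HR and 0 in ER. It was at least 15.6-fold lower by its counting interval, and 19.9-fold lower with ER set at a floor of 3 counts in that library. The genes higher in ER held 52.6% of the ER counts and 14.9% of the HR counts, and those lower in ER held 50.2% of the HR counts and 10.7% of the ER counts. Among the higher genes, F959_RS16585 alone held 24.5% of the ER counts and 8.4% of the HR counts. The median length was 835.5 bp for the higher genes and 705 bp for the lower genes. The whole counting interval lay beyond 2-fold for 452 of the higher and 411 of the lower genes. These libraries differ in planktonic or biofilm growth, in the culture system and in culture time as well as in the mode of respiration.

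**Figure D1:**
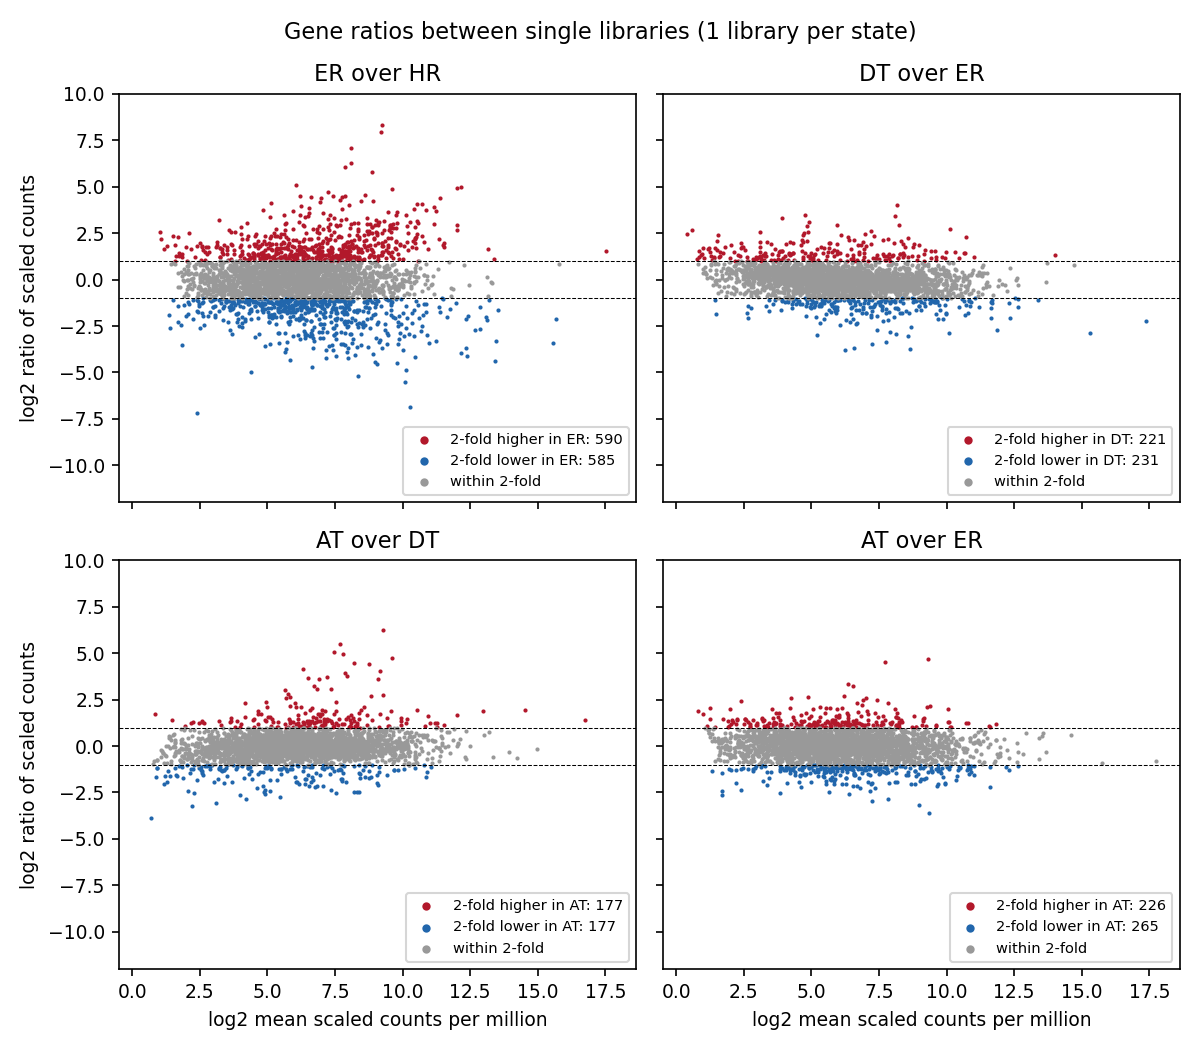
Log2 ratio of TMM-scaled counts (vertical axis) against the log2 mean CPM (horizontal axis) for each gene with at least 20 counts, in 4 panels, 1 per comparison; red and blue points are genes at least 2-fold higher or lower, grey points the rest, and dashed lines mark 2-fold. ER over HR has 590 and 585 coloured genes, against 221 and 231 for DT over ER, 177 and 177 for AT over DT, and 226 and 265 for AT over ER.

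The comparison of DT with ER sets a biofilm library from the BOD test, at the lowest current, against a biofilm library at the baseline current. Each library is a separate sample, and the titles give days on the cathode for ER only. Differences in electrode or biofilm age between ER, DT and AT can therefore not be separated from the state. Of 3179 genes compared, 221 were at least 2-fold higher in DT and 231 at least 2-fold lower, and 5 and 7 differed at least 8-fold. F959_RS06655 (1071 bp) stood at 539.6 CPM in DT and 32.9 in ER, 16.4-fold higher (14.2 to 19.1), with 6.36 in HR and 98.5 in AT. F959_RS16045 (801 bp) was 11.2-fold higher (7.61 to 17.8), at 49.8 in DT and between 4.38 and 9.04 in the other libraries. F959_RS11430 (1209 bp) was 13.9-fold lower in DT (11.2 to 17.6), at 10.1 against 141 in ER, and F959_RS11425 (1356 bp) was 13.6-fold lower (12.4 to 15.0), at 55.2 against 750.0. The 2 short genes with the highest shares in ER were among the lower genes, F959_RS16585 with a log2 ratio of -2.25 and F959_RS16390 with -2.90. Genes lower in DT held 46.5% of the ER counts and 17.7% of the DT counts. The balance of directions depended on the scaling: 650 genes were higher and 71 lower when libraries were scaled by total counts, which moved the median of all genes by 0.56 on the log2 scale, and 90.2% of the genes counted were then higher, against 48.9% with TMM. The 319 genes with the lowest HR level per kilobase had a median log2 ratio of 0.37, and with an even background taken off DT, an alternative chosen after seeing the data, 173 genes were higher and 282 lower, or 38.0% higher. The whole counting interval lay beyond 2-fold for 125 of the higher and 162 of the lower genes.

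The comparison of AT with DT asks what differs once the test liquid has been replaced. Of 3181 genes compared, 177 were at least 2-fold higher in AT and 177 lower, and 19 were at least 8-fold higher against 3 at least 8-fold lower. F959_RS09695 (1275 bp) stood at 1215 CPM in AT and 16.04 in DT, 75.4-fold higher (64.1 to 90.1), and F959_RS09690 (1206 bp) stood at 401 and 8.76, 45.4-fold higher (36.5 to 58.1). Both were high in HR as well, at 2147 and 636. The lowest ratios belonged to weakly counted genes. F959_RS14320 (576 bp) had 6 counts in AT and 73 in DT, 9.23-fold lower (4.36 to 28.0), and F959_RS15070 (1323 bp) had 13 and 136, 8.26-fold lower (4.84 to 16.5). The higher genes held 30.4% of the AT counts and 12.7% of the DT counts, with F959_RS16585 among them at a log2 ratio of 1.42. Scaling by total counts gave 113 higher and 323 lower genes, 25.9% higher against 50% with TMM, and moved the median of all genes by -0.272 on the log2 scale. An even background taken off DT gave 241 and 146, or 62.3% higher. The whole counting interval lay beyond 2-fold for 133 of the higher and 95 of the lower genes.

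The comparison of AT with ER asks how far the library after recovery lay from the library at the baseline current. Of 3148 genes compared, 226 were at least 2-fold higher in AT and 265 at least 2-fold lower, and 26 and 29 differed at least 4-fold. F959_RS09695 was 25.7-fold higher in AT than in ER (22.8 to 29.1), at 1215 against 47.3, and F959_RS09690 was 22.8-fold higher (18.8 to 28.2). F959_RS08475, the gene with the highest ratio of ER to HR, was 12.1-fold lower in AT than in ER (11.2 to 13.1), at 99.6 CPM. F959_RS13330 (234 bp) was 8.93-fold lower (8.26 to 9.66), at 102 in AT against 912 in ER, 569 in DT and 48.1 in HR. Total-count scaling gave 430 higher and 126 lower genes, 77.3% higher against 46.0% with TMM, and moved the median of all genes by 0.285 on the log2 scale. The whole counting interval lay beyond 2-fold for 108 of the higher and 163 of the lower genes.

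**Figure D2:**
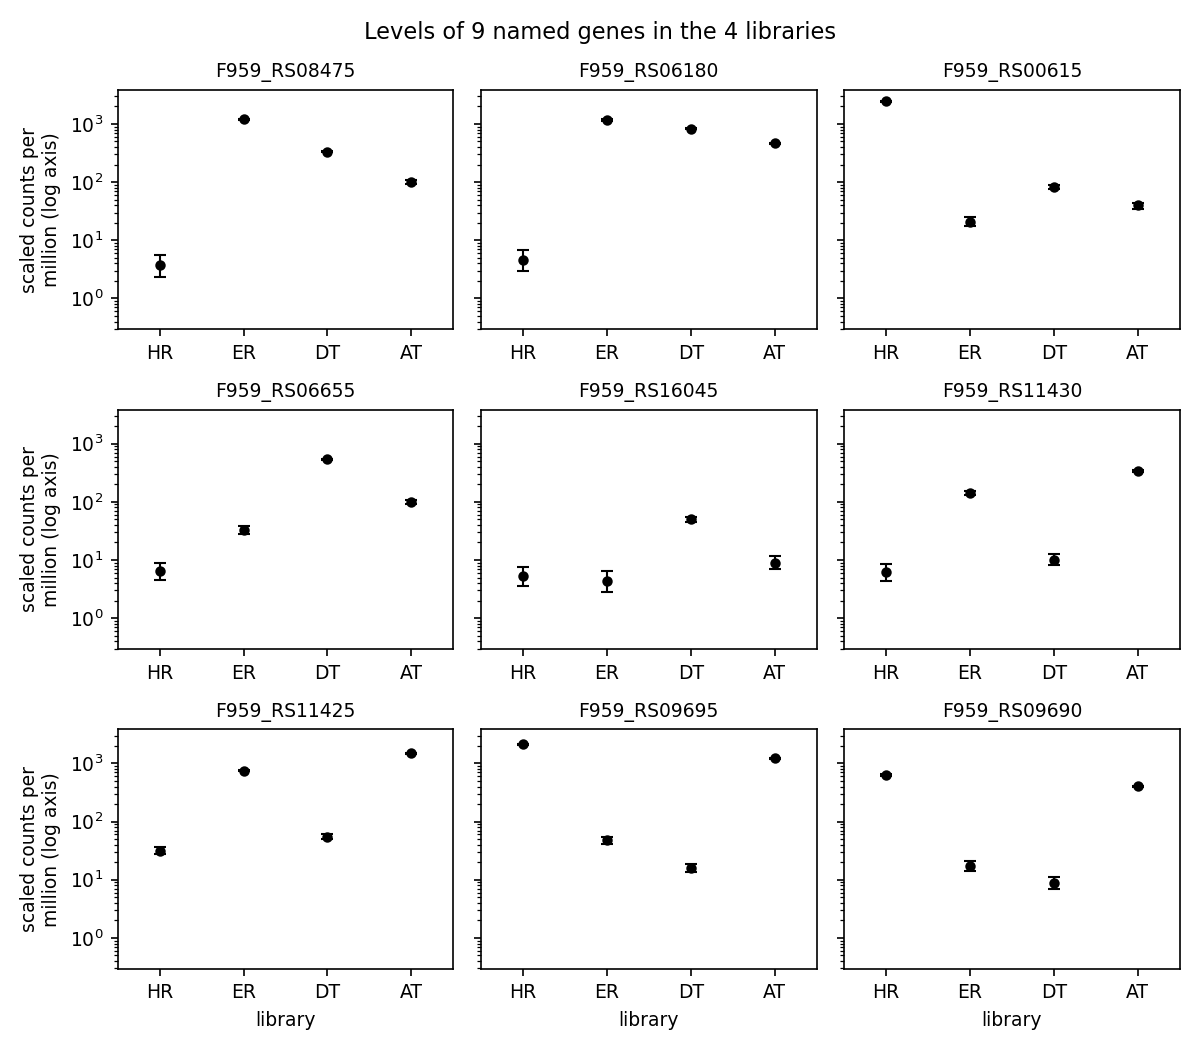
TMM-scaled CPM (log axis) of 9 genes named for their ratios in the 4 libraries (HR, ER, DT, AT); points are single libraries and bars are exact 95% Poisson intervals for counting error. F959_RS06655 and F959_RS16045 are highest in DT, F959_RS11430 and F959_RS11425 are high in ER and AT and low in DT, and F959_RS09695 and F959_RS09690 are high in HR and AT.

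Over the 3 biofilm libraries, 2348 of 3184 genes (73.7%) stayed within 2-fold in every pair. In 431 genes at least 1 library lay 2-fold or more from both of the others on the same side. A gene could meet this for more than 1 library and was then counted under each, also where a library is said below to differ alone. DT lay apart in 167 genes, 100 of them higher in DT than in ER and AT, and 67 lower. ER lay apart in 175 genes, with 110 higher in ER than in DT and AT, and 65 lower. AT lay apart in 131, with 80 higher and 51 lower. With single libraries, genes in which DT lies apart cannot be separated from differences peculiar to the DT library, and the counts for DT, ER and AT were of like size. Taking an even background off DT changed the 100 and 67 to 86 and 92, and scaling by total counts changed them to 186 and 33. For ER alone the balance turned with the scaling: by total counts 25 genes were higher in ER and 217 lower, in place of 110 and 65. For AT alone total counts gave 71 higher and 53 lower.

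The HR level was set beside each of these sets of genes. HR and the lone library are both measured against the same mean of the other biofilm libraries, so an error in that mean moves both alike. For a gene counted under another library as well, the levels in that mean themselves differed at least 2-fold. No count for independent lists was computed for these sets. Of the 80 genes higher in AT alone, HR was also at least 2-fold above the mean log level of ER and DT in 49, and at least 2-fold below it in 9. Of the 110 genes higher in ER alone with TMM scaling, HR was at least 2-fold below the mean of DT and AT in 55 and at least 2-fold above it in 9. Of the 100 genes higher in DT alone, HR lay within 2-fold of the mean of ER and AT in 57, at least 2-fold above it in 21 and at least 2-fold below it in 22. Of the 67 genes lower in DT alone, HR was at least 2-fold below that mean in 30 and at least 2-fold above it in 15. Of the 65 genes lower in ER alone, HR was at least 2-fold below the mean of DT and AT in 16, at least 2-fold above it in 17 and within 2-fold in 32. Of the 51 genes lower in AT alone, HR was at least 2-fold below the mean of ER and DT in 21, at least 2-fold above it in 4 and within 2-fold in 26.

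**Figure D3:**
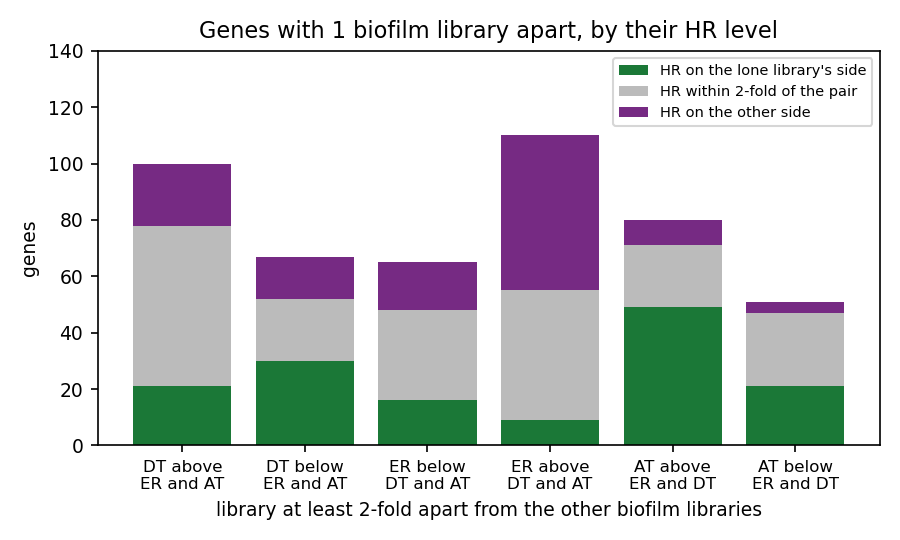
Number of genes (vertical axis) in which 1 biofilm library lay at least 2-fold from both others, by which library and which side (horizontal axis); colours give where the HR level lay against the mean of the other biofilm libraries (at least 2-fold on the lone library's side, within 2-fold, or at least 2-fold on the other side). HR lay on the side of the lone library in 49 of the 80 genes higher in AT alone, and in 21 of the 100 genes higher in DT alone. For the lower genes it did so in 21 of 51 for AT and in 30 of 67 for DT.

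To compare directions without sharing a library between the ratios, each pair of biofilm libraries was set against the remaining pair over the 3186 genes with at least 20 counts in any of the 4 libraries, so the numbers of higher and lower genes differ slightly from those above. Of 233 genes higher in AT than in ER, 105 were also higher in HR than in DT, where independent lists would share 37.1, and of 270 genes lower in AT than in ER, 108 were lower in HR than in DT, against 41.5. Of 178 genes higher in AT than in DT, 81 were higher in HR than in ER, against 32.9, whereas 41 of the 177 lower genes were lower in HR, against 33.4. Of 232 genes lower in DT than in ER, 102 were lower in HR than in AT, against 31.4, and of 223 genes higher in DT, 54 were higher in HR, against 28.6. Across genes, which are not independent replicates, Pearson's r of these ratios was 0.352, 0.187 and 0.175, in the order given. In opposite directions, 30 of the genes higher in AT than in ER were lower in HR than in DT, against 35.8, and 14 of the lower ones were higher, against 43.0. For AT and DT these numbers were 34, against 33.6, and 33, against 32.7. For DT and ER they were 41, against 30.2, and 28, against 29.8.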

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

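The background taken off DT was chosen after seeing the data. Of 138 recomputed counts of genes, 116 stayed within 1.5 times the reported count, and no named gene changed direction among 104 recomputed ratios, 11 of which left the gene's counting interval. Median-of-ratios scaling, TMM without the 20 most counted genes, the deposited FPKM, both other count filters, a prior count of 5, thinning, and the background taken off DT left every count of genes within 1.5 times. The deposited FPKM carry the median-of-ratios factors, and thinning changed the library totals little, so these settings are not separate checks. Scaling by total counts gave 650 genes higher and 71 lower in DT than in ER, 113 and 323 in AT than in DT, and 430 and 126 in AT than in ER, and moved the median of all genes by the ratio of the scaling factors. It gave 186 and 33 genes with DT alone higher or lower, and 217 and 25 with ER alone lower or higher. For ER against HR it gave 590 and 578. Requiring the whole counting interval beyond 2-fold, a narrower criterion by construction, counted 125 genes higher in DT than in ER, 95 lower in AT than in DT, and 108 higher and 163 lower in AT than in ER. At 4-fold, 197 and 196 genes were counted for ER against HR, 36 and 32 for DT against ER, 34 and 28 for AT against DT, and 26 and 29 for AT against ER. The gene list alternatives were not run because the lists matched no gene, and no replicate could be left out because each state has 1 library. Depth limits single ratios only at low counts; the lack of replicates limits all of them.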

Other observations

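The tests below were chosen after seeing the data, except the earlier ones on admixture of HR-type RNA (the share of genes under a set level, and the genes higher in ER), which were set down before their own values. For the share of genes, the need for a minimum number of informative genes was added after its value was seen, and the test on genes higher in ER was added after that.

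Genes with consecutive locus tags differed together. For ER over HR, the correlation of log2 ratios between consecutive tags was 0.397 over 2990 pairs, against at most 0.055 in 1000 shuffled orders and 0.049 between tags 50 places apart. It was 0.491 for DT over ER, 0.492 for AT over DT and 0.418 for AT over ER. Runs of at least 5 consecutive tags that all differed at least 4-fold in the same direction numbered 9 for ER over HR (58 genes), 2 for DT over ER, 3 for AT over DT and 1 for AT over ER. Shuffled orders gave at most 1 such run for ER over HR and 0 for the others. A candidate explanation is that tags follow the chromosome and that these runs are transcribed together, which was not tested against an annotation.

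Of these runs, 4 distinct ones hold genes named for their ratios and were picked after their values were seen, so their size is no independent evidence. A run of 13 genes with F959_RS11425 and F959_RS11430 had a median ratio 12.2-fold higher in ER than in HR, 5.46-fold lower in DT than in ER and 15.6-fold higher in AT than in DT. In AT all 13 were at least 2-fold above ER. A run of 7 genes with F959_RS09690 and F959_RS09695 was 13.6-fold lower in ER than in HR by its median, 12.3-fold higher in AT than in DT and 6.61-fold higher in AT than in ER. Its summed level was 4176 scaled CPM in HR, 166 in ER, 110.2 in DT and 2246 in AT. A run of 5 genes with F959_RS16045 summed to 20.7 CPM in HR, 60.04 in ER, 389 in DT and 106 in AT. A run of 5 genes with F959_RS06655 summed to 44.5 CPM in HR, 1024 in ER, 3570.2 in DT and 1433 in AT.

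The AT library lay nearer to HR than ER did: scaling is argued against by the rank correlation with HR, which no scaling moves and which was higher by 0.059 for AT than for ER, and a gene length trend by the SD of the log2 ratios against HR, which after its removal was 0.792 times as large for AT as for ER. An even admixture of HR-type RNA needs 1 share for all genes, while 126 genes high in HR lay at a median of 9.43% of the way from ER to HR in AT (quartiles 4.44% and 18.66%, and 0.49% in DT), but only 8 of them were able to fall under the level set for the test and 1 of these did (0.8% of the 126). Over 790 genes abundant in HR, the upper counting limit of AT over HR was 1.82% for the lowest gene and 7.68% for the gene ranked 5 from the bottom. With 7.68% of the HR level taken off AT, its rank correlation with HR exceeded that of ER by 0.023 (95% bootstrap interval over genes 0.012 to 0.034). The bootstrap drew genes singly, although neighbours in the tag order differed together, so this interval is likely too narrow. It also covers no difference between cultures. With the median share of 9.43% taken off, the excess was 0.009, but 9 of the 790 genes had upper limits under that share. Admixture as the whole cause predicted at most 0 and its absence over 0.02. The value at 7.68% lay above 0 but was not clear of 0.02, so this test neither bore admixture out nor excluded it. For the 197 genes at least 4-fold higher in ER than in HR, the median log2 ratio to ER was -0.99 in AT and -1.01 in DT. Admixture at the median share would give -0.12 in AT, but the gap cannot be told apart from the choice of genes for a high ER value. The rule set for this test also asked for a clearly lower median in AT than in DT. That was not met, so the test decided nothing. The ratio of HR to DT does not use ER. Of the 270 genes lower in AT than in ER, 108 were lower in HR than in DT, against 41.5, and 14 were higher, against 43.0. An even share of 9.43% cannot lower a gene 2-fold, but these genes were chosen for a fall of that size. A direction shared with HR is also what admixture predicts. Within single libraries and TMM scaling, such a share alone does not account for these 2-fold falls. Whether it caused smaller falls, or AT lying nearer to HR, stays open. For the genes higher in AT, even admixture stays open as well. A difference in the state of the biofilm, which the design names, remains untested.

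Genes with low counts were higher in DT than in ER: the 319 genes with the lowest HR level per kilobase had a median log2 ratio of 0.37, the next 319 had 0.08, and the medians of the higher groups went from 0.04 down to -0.12. A candidate explanation is an even background of reads along the genome in DT, such as residual DNA, which would add a like level per kilobase to genes of any level. Measured from the median log2 ratio of -0.09 of the genes in the upper 5 of 10 groups, the added level was 2.47 scaled CPM per kilobase in the lowest group and 2.04 in the next, a ratio of 0.83 (95% bootstrap interval 0.46 to 1.27). Its median was 1.13 to 2.44 in groups 3 to 8 from the bottom, -3.58 in group 9 and -11.25 in group 10. Measured from a log2 ratio of 0, the added level was 1.89 and 0.88 in the 2 lowest groups, a ratio of 0.47 (-0.05 to 0.95). It then went from -0.65 in group 4 down to -41.26 in group 10. The test therefore rests on the offset chosen and leaves the background open. Weak transcription of many genes in DT would look alike and was not tested.

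F959_RS16585 and F959_RS16390 together took 30.7% of the counts in ER, 20.7% in AT, 11.9% in HR and 8.81% in DT. By their median, short genes in general did not fall in DT as these genes did. The median log2 ratio of DT to ER was -0.13 for the 470 other genes of up to 400 bp. The ratio was -2.25 for F959_RS16585 and -2.90 for F959_RS16390. The 24 compared genes of 70 to 100 bp whose length is no multiple of 3 had a median of -0.05. These are gene lengths, and the lengths of the RNAs were not measured, so poorer recovery of short RNAs in DT stays open. A difference in the amount of RNA from F959_RS16585 and F959_RS16390 in the cells also stays open and was not tested. So does a difference in how abundant RNAs came through rRNA depletion in each library.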
